A study of Mus musculus with 6 samples.

How the data were processed

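RNA sequencing libraries were made from CD11b-positive bone marrow cells, which were purified with a positive selection kit from tibias of mice aged 12 weeks. Total RNA was the input and a SMARTer mRNA kit the library method, per the labels' protocols. The titles number the mice 1 to 3 in each genotype, which is read as 1 animal per library. The p-values of single genes compared between the groups measure the spread between these libraries. The titles call the mutant animals Tshr-/-, while another label calls them a knockdown; the title was followed. A label names osteoclast differentiation as treatment and no time for it, and no culture step is described, so the cells are described only as CD11b-positive bone marrow cells.

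The deposited table holds 1 row for each of 54532 genes and 1 column of FPKM values for each of the 6 libraries, with the length and position of each gene. The columns are headed WT and HO with the numbers 1 to 3; HO was read as homozygous Tshr-/- and each number as that of the title, since the labels give no other genotype beside wild type, and the table does not spell HO out. FPKM are fragments scaled to the length of the gene and the size of the library, made by the authors from their read alignments. The builds GRCm38 and mm10 are named, per the submitters' processing notes; the aligner, the counting tool, its use of strand and their versions are not given in the sources used here. Gene positions equalled those of GENCODE release M21 for 53585 of 54495 matched identifiers. The deposited FPKM of each library, multiplied by gene length, were whole multiples of 1 step per library in 100% of values within 0.01, so whole fragments could be computed. The library size behind the deposited FPKM was between 0.939 and 1.12 times the sum of fragments, and equalled a median-of-ratios factor times the geometric mean of the sums with a ratio of 1 in all 6 libraries, so the values carry a scaling between libraries already. The libraries held 14698126 to 17976477 fragments, and 1 fragment of a gene of 1 kb was worth between 0.0496 and 0.0713 FPKM. Mitochondrial genes took between 0.592% and 0.762% of fragments, and the 10 most abundant genes between 11.4% and 14.2%. Counts of every pair of libraries differed by more than sampling noise (smallest chi-square per degree of freedom 9.77), so no library was counted as a copy of another.

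The main comparison was fixed before the data were examined. FPKM were used as deposited and put on the scale log2(FPKM + 1), and genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, 10913 in all, of which 9177 are protein coding and 425 averaged under 10 fragments. The group means were compared with limma 3.58.1 in R 4.3.3 (linear model by group, empirical Bayes with a trend in the variance, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). A fold change is on the log2(FPKM + 1) scale, which understates the change of genes with low values. Count models had been planned only for a deposited file of counts and were not used; the whole fragments computed from FPKM were tested with voom as an alternative. Of 31 fixed gene lists, 30 had at least 5 tested members and were compared with all other genes with limma's camera at a preset correlation of 0.01; the list of sex-linked genes is reported as values. At the preset correlation, camera compares genes with genes under an assumed correlation, so its p-values do not measure the spread between libraries. Camera with an estimated correlation and fry were the alternatives. The lists share some genes: Irf7 and Bst2, for example, stand in the interferon list and in that of dendritic cells. Tshr fell below the filter, so its group means were compared with an exact permutation test; intervals of its counts are exact Poisson intervals at 95% and cover counting error only. Calls near Tshr were compared with Fisher's exact test, which counts genes and not libraries.

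Genes were named by a rule: Tshr first, then the genes past the threshold, and where fewer than 5 passed in a direction, the 5 with the smallest p there that had a mean of at least 5 FPKM in the higher group, groups that did not overlap and a symbol that is not a predicted model; and from each list the members past the threshold or, if none, the 2 with the smallest p and the most abundant. Of these, the text names those that describe each group. Genes outside the rule are marked in the text as named after their values were seen.

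Alternatives included other pseudocounts, other filters, rescaling to equal totals, median-of-ratios and quantile scaling, robust variance moderation, array weights, the replicate number as a block and each library left out. Chosen after seeing the data were limma's voom on whole fragments of genes with at least 10 fragments in at least 3 libraries, protein-coding genes alone, a minimum of 10 fragments, leaving out both libraries numbered 3, and leaving out the libraries labelled Tshr-/- 1 and 2, the last because of their level of Tshr. Replicate numbers of the titles pair the samples by the check used here: deviations from the group means of same-numbered libraries correlated across genes with r = 0.24, 0.26 and 0.47. Genes are not independent replicates, Tshr+/+ 2 correlated more with Tshr-/- 1 (r = 0.34) than with its own number, and the labels do not say what a shared number stands for.

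The fits were tested on simulated fragments with the means, library sizes and spread of these libraries. For the simulated comparison of the 2 genotypes over 10913 genes, limma recovered 48 of 100 genes changed 2-fold and 81 of 100 changed 4-fold, with 13 of 10683 unchanged genes called, and 0 of 29 unchanged lists passed. That simulation holds no correlation between genes, so it does not test the preset correlation. Its changed genes were drawn from those above a minimum mean of fragments, so recovery of genes with few fragments was not measured. Values were handled with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.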

Results

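Gene expression was measured by RNA sequencing in CD11b-positive bone marrow cells of mice of 2 genotypes. CD11b is an integrin chain on the surface of myeloid cells, and cells that carry it include neutrophils, monocytes, macrophages and precursors of osteoclasts, the cells that resorb bone. The cells came from the tibias of animals aged 12 weeks. The titles number the mice of each genotype, so that 3 libraries are labelled Tshr+/+ (wild type) and 3 Tshr-/-. Tshr encodes the receptor of thyroid-stimulating hormone, and the title of the study names protection of bone by that hormone and AMPK signalling in osteoclasts. The comparison of the 2 genotypes asks which genes of these cells differ when the receptor is missing. The libraries held between 14698126 and 17976477 fragments assigned to genes, and between 20762 and 21358 genes had a value above 0. S100a8 and S100a9, the calprotectin genes of neutrophils, took between 4.06% and 5.18% of the fragments of a library.

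Tshr itself was still present in 2 of the 3 libraries labelled Tshr-/-. The gene (ENSMUSG00000020963) lies on chromosome 12 from 91384563 to 91549808 of GRCm38, on the plus strand. The libraries labelled Tshr+/+ held 0.537, 0.552 and 0.405 FPKM of Tshr, from 55, 55 and 45 fragments. The library labelled Tshr-/- 1 held 0.414 FPKM from 40 fragments (exact 95% Poisson interval 0.295 to 0.563), and the library labelled Tshr-/- 2 held 0.297 FPKM from 25 fragments (0.192 to 0.438). The library labelled Tshr-/- 3 held 0.00825 FPKM from 1 fragment (0.000209 to 0.0460), where 60.3 fragments would have matched the wild-type mean. The means were 0.498 ± 0.0811 FPKM (SD, n = 3) in Tshr+/+ and 0.239 ± 0.209 FPKM (SD, n = 3) in Tshr-/-, a difference that did not pass an exact two-sided permutation test (p = 0.2, where 0.1 is the smallest p that 3 against 3 libraries allow). The values cover the whole gene model, and the labels do not say which part of Tshr the mutation removes. Fragments from a retained part of the gene would thus be counted here too. In the annotation 1 other gene overlaps Tshr on the same or opposite strand, and the use of strand in counting is not given. Whether fragments of that gene were counted as Tshr was not tested. Fragments of Tshr in the libraries labelled Tshr-/- 1 and 2 therefore leave open whether these libraries match their label. For that reason each group is named by its label, and every direction given is that of the labels.

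**Figure D1:**
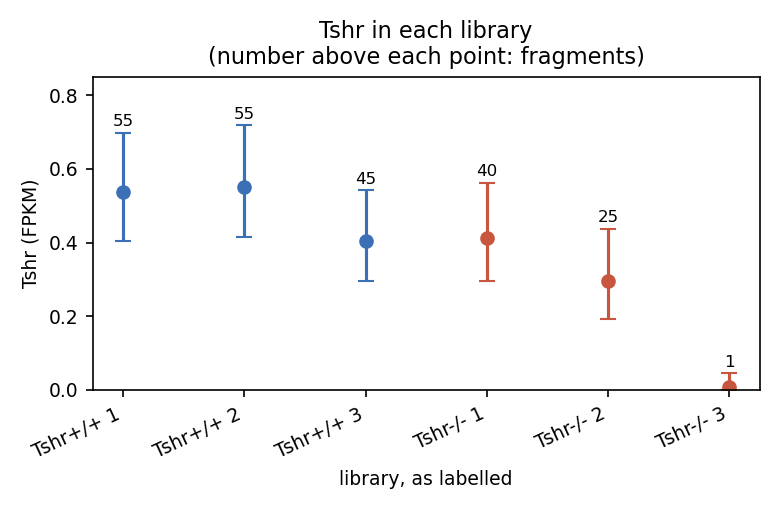
Tshr in each library in FPKM (y axis), with the number of fragments above each point and exact 95% Poisson intervals of counting error as bars; blue marks libraries labelled Tshr+/+ and red those labelled Tshr-/-. The library labelled Tshr-/- 3 sits at 0.00825 FPKM, and the other libraries lie between 0.297 and 0.552 FPKM.

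No gene differed between the libraries labelled Tshr-/- and those labelled Tshr+/+ past the threshold. Among the genes that the naming rule admits, those nearest on the higher side included Nlrc5, an activator of MHC class I genes (chromosome 8, 94434356 to 94527272; 3.20 ± 0.226 FPKM in Tshr+/+ and 5.43 ± 0.614 FPKM in Tshr-/-, SD, n = 3), Slfn5, a Schlafen family gene induced by interferon (chromosome 11, 82951349 to 82964840; 5.75 ± 1.51 and 10.6 ± 1.14 FPKM), and Dtx3l, a ubiquitin ligase gene (chromosome 16, 35926511 to 35939151; 3.95 ± 1.00 and 6.66 ± 0.643 FPKM). Ssh2, a phosphatase of the actin regulator cofilin, and Kidins220, a membrane scaffold protein, also had all Tshr-/- values above all Tshr+/+ values, with log2 fold changes of 0.49 ± 0.10 (SE) and 0.38 ± 0.09 (SE). On the lower side stood the cell adhesion gene Mcam (5.93 ± 1.10 and 3.43 ± 0.274 FPKM), the microRNA precursor gene Mir142b (chromosome 11, 87756841 to 87756955; 76.4 ± 7.43 and 46.8 ± 2.07 FPKM) and the immunoglobulin segments Iglc1 (21.4 ± 4.53 and 8.15 ± 2.81 FPKM), Igkv3-2 and Igkv15-103. Igkv3-2 had a log2 fold change of -1.16 ± 0.21 (SE) and Igkv15-103 of -1.17 ± 0.28 (SE).

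These 10 genes did not pass: limma gave an adjusted p of 0.933 for Mir142b and of 0.9997 for the others. Of 10913 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.566, for the microRNA gene Mir744 with a mean of 1.33 fragments, which is outside the naming rule. Dsp and Gbp7 were left out by their low means and are named after their values were seen. They had log2 fold changes of -1.29 ± 0.24 (SE) and 0.59 ± 0.14 (SE), each at an adjusted p of 0.9997. At an unadjusted p under 0.05 stood 317 genes, 156 higher and 161 lower, where 545.65 would be expected if no gene differed. The groups did not overlap for 739 genes, or 6.77%, against the 10% that chance gives for 3 against 3. The voom method of limma on whole fragments also called 0 of 13709 genes. Array weights, which give each library its own weight, called 13 higher and 11 lower genes. Among them were Nlrc5, Slfn5, Dtx3l, Trim30a, Mcam, Mir142b, Iglc1 and Igkv3-2. Also called were genes with few fragments, such as Mir744, Mir6362 with a mean of 1 and Mir6399 with 2.17, named after their values were seen. The weights were 3.82 for the library labelled Tshr-/- 1 and 3.15 for Tshr+/+ 2, and between 0.247 and 1.25 for the others. These calls thus lean on few libraries. Leaving out the library labelled Tshr-/- 3 called 2 higher genes, the pseudogenes BC002163 and Gm3375, named here after their values were seen. In simulated data of the same size and spread, limma recovered 48 of 100 genes changed 2-fold and 81 of 100 changed 4-fold. The simulated genes varied independently and the changed ones lay above a minimum mean of fragments, so recovery in the real libraries may differ. Mir142b overlaps Mir142 and its host gene on the opposite strand and the immunoglobulin segments resemble each other, so their fragments may have been divided between genes; the use of strand in counting is not given in the sources used here.

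Genes of the interferon response held higher values in the libraries labelled Tshr-/-. All 34 tested members of that list had a log2 fold change above 0, with a median of 0.41, and in 9 of them the 3 Tshr-/- values lay above the 3 Tshr+/+ values, where chance gives 10% without overlap in either direction. Slfn5 had a log2 fold change of 0.80 ± 0.17 (SE), the ubiquitin ligase gene Trim30a of 0.53 ± 0.14 (SE), and the abundant membrane protein gene Ifitm3 of 0.01 ± 0.15 (SE). Ifit1, which encodes a protein that binds viral RNA, had 3.71 ± 0.930 FPKM in Tshr+/+ and 8.25 ± 2.81 FPKM in Tshr-/- (SD, n = 3), Ifit3 of the same family had 6.97 ± 1.86 and 12.9 ± 3.06 FPKM, and Rsad2, the antiviral enzyme viperin, had 14.0 ± 1.46 and 27.2 ± 10.8 FPKM. Ifit1, Ifit3 and Rsad2 were picked from the list after their values were seen. Their higher means rest mainly on the libraries labelled Tshr-/- 1 and 2. In the library labelled Tshr-/- 3 they had 5.01, 9.38 and 14.9 FPKM, near the highest Tshr+/+ values of 4.68, 9.08 and 15.4 FPKM. Ifi44l and Ifi44, interferon-induced genes outside the list that were also named after their values were seen, go against it: Ifi44l had 3.75 ± 2.26 and 2.19 ± 3.79 FPKM, with 0 FPKM in the libraries labelled Tshr-/- 1 and 2, and Ifi44 had 1.16 ± 0.441 and 1.01 ± 1.42 FPKM.

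The interferon list ranked above the other genes with limma's camera test at a preset correlation between genes of 0.01 (adjusted p = 1.27e-20). The correlation between its genes estimated from the data was 0.284, far above the preset value, and at that estimate the preset p is too small. Adjusted over 30 lists, it did not pass with the estimated correlation (camera adjusted p = 0.766, unadjusted p = 0.0255). The list did not pass with fry either, which tests the list by itself (adjusted p = 0.935, unadjusted p = 0.0328). None of its members passed over all genes or adjusted over the list alone (0 genes). Relative to the Tshr+/+ mean, the mean log2 value of the list was 0.63 higher in the library labelled Tshr-/- 1, 0.55 higher in the library labelled Tshr-/- 2 and 0.24 higher in the library labelled Tshr-/- 3, while the Tshr+/+ libraries lay between -0.23 and 0.13. Without the libraries labelled Tshr-/- 1 and 2, an alternative chosen after seeing the data, the median was 0.26.

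**Figure D2:**
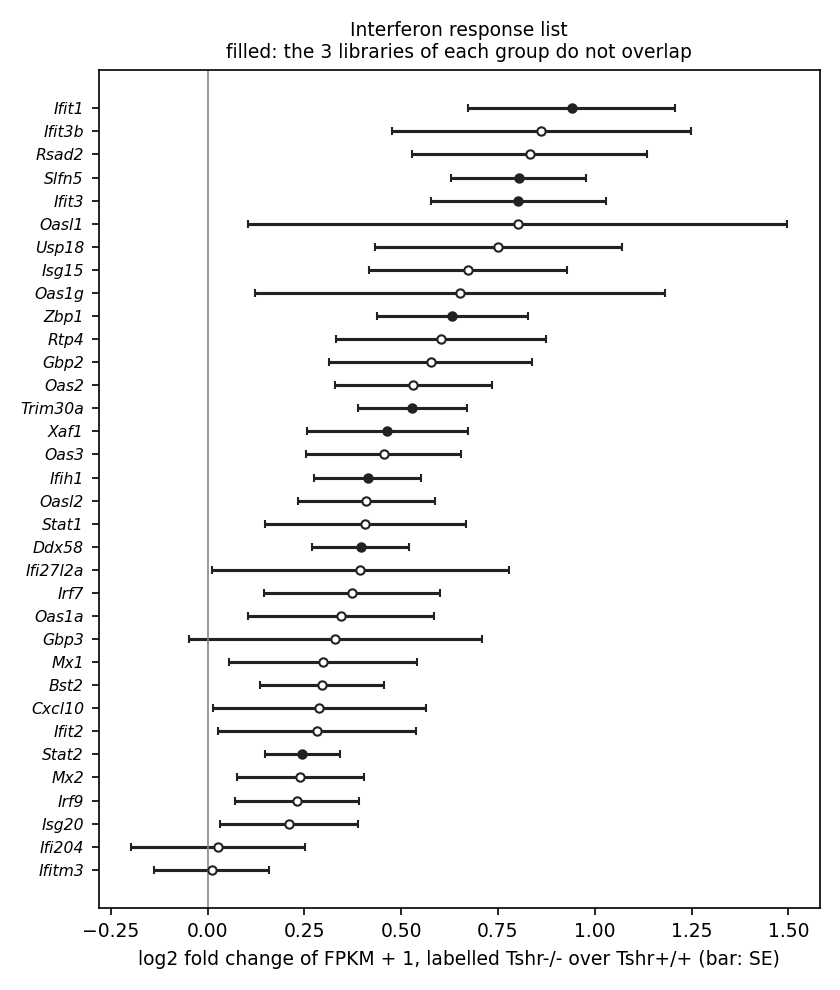
Log2 fold change of FPKM + 1 (x axis, libraries labelled Tshr-/- over Tshr+/+) for the 34 tested genes of the interferon response list, with SE as bars; filled points mark genes whose groups do not overlap. All 34 points lie above 0, from 0.01 for Ifitm3 to 0.94 for Ifit1, and none passed the test of single genes.

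Genes of osteoclast formation and of the pathways the study names did not pass as lists. Among 15 tested osteoclast genes 9 had a higher and 6 a lower value in the libraries labelled Tshr-/-, with a median log2 fold change of 0.03 (camera adjusted p = 0.337). The sorting nexin gene Snx10 had 7.03 ± 0.681 FPKM in Tshr+/+ and 8.31 ± 0.310 FPKM in Tshr-/- (SD, n = 3), and the proton pump subunit gene Atp6v1c1 had 9.87 ± 0.644 and 8.82 ± 0.475 FPKM. Tyrobp, an adaptor of immune receptors, was the most abundant of the list at 1259 ± 95.9 and 1271 ± 228 FPKM. Acp5, the tartrate-resistant phosphatase of osteoclasts, had 7.68 ± 3.62 and 15.1 ± 12.6 FPKM, and the library labelled Tshr-/- 2 alone reached 29.7 FPKM. The collagen-degrading protease gene Ctsk also had a single high library, with 37.4 FPKM there and 5.51 and 6.43 FPKM in the libraries labelled Tshr-/- 1 and 3. Acp5 and Ctsk were picked from the list after their values were seen.

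The AMPK signalling list had a median log2 fold change of -0.02 over 39 tested genes (camera adjusted p = 0.790). Srebf1, a regulator of lipid synthesis, and Camkk1, a kinase that phosphorylates AMPK, had log2 fold changes of -0.29 ± 0.12 (SE) and -0.23 ± 0.13 (SE), and neither passed. The list of RANK, NF-kB and MAPK signalling had a median of -0.01 over 29 genes (adjusted p = 0.944) while its test pointed upward, and Traf3 and Tnfaip3, inhibitors of NF-kB signalling, had log2 fold changes of 0.19 ± 0.11 (SE) and 0.36 ± 0.30 (SE). Over 17 genes of cAMP and PKA signalling, a pathway downstream of the receptor, the median was -0.07 (adjusted p = 0.602), and Prkar2a, a regulatory subunit of PKA, had 8.52 ± 2.27 and 5.27 ± 1.22 FPKM. At the preset correlation that list passed without both libraries numbered 3 (median -0.25, adjusted p = 0.00974), an alternative chosen after seeing the data. With an estimated correlation, which was run on all 6 libraries only, its adjusted p was 0.928. The autophagy list had a median of -0.03 over 29 genes (adjusted p = 0.736), with the kinase gene Ulk2 at 4.87 ± 0.134 and 5.86 ± 0.679 FPKM. The list of the thyroid hormone axis had a median of 0.13 over 10 genes (adjusted p = 0.108), with Klf9, a thyroid hormone response gene, at 5.69 ± 1.83 and 7.95 ± 2.30 FPKM. Its median rests on Tshr+/+ 3: without that library it was 0.02 (adjusted p = 0.847), and without both libraries numbered 3 it was -0.01. At the preset correlation the list passed without Tshr+/+ 1 (adjusted p = 0.0281), Tshr+/+ 2 (0.0420) or Tshr-/- 2 (0.0389), with a mean of at least 5 FPKM (0.0399) and without the libraries labelled Tshr-/- 1 and 2 (0.0310), while its adjusted p was 0.922 with an estimated correlation on all 6 libraries.

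Among the lists of cell types, genes of neutrophil primary granules, T and NK cells and erythroid cells ranked higher in the libraries labelled Tshr-/-, and genes of resident macrophages ranked lower, with the preset correlation only. The primary granule list had a median log2 fold change of 0.16 over 14 genes, and its proteases Prtn3 (379 ± 42.6 FPKM in Tshr+/+ and 473 ± 52.1 FPKM in Tshr-/-, SD, n = 3) and Elane (1007 ± 119 and 1138 ± 152 FPKM) overlapped between the groups. The T and NK cell list had a median of 0.33 over 7 genes, with the granzyme gene Gzma at 4.30 ± 0.831 and 7.66 ± 1.70 FPKM. The erythroid list had a median of 0.56 over 7 genes, with the haemoglobin genes Hbb-bs at 31.6 ± 15.1 and 50.9 ± 12.8 FPKM and Hba-a1 at 36.1 ± 18.8 and 50.7 ± 14.2 FPKM. The resident macrophage list had a median of -0.14 over 21 genes, with the lipoprotein gene Apoe at 147 ± 27.5 and 96.2 ± 12.2 FPKM, and Trf, the gene of the iron carrier transferrin, at 3.60 ± 0.568 and 2.48 ± 0.207 FPKM.

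The camera adjusted p with the preset correlation was 0.00170 for the primary granule list, 0.00553 for the resident macrophage list, 0.01003 for the T and NK cell list and 0.0176 for the erythroid list. Each had an adjusted p = 0.922 with an estimated correlation. That estimate was 0.509 for the primary granule list, 0.620 for resident macrophages, 0.296 for T and NK cells and 0.103 for erythroid cells, all above the preset 0.01. With the replicate number as a block, the T and NK cell list no longer passed (adjusted p = 0.0506). The primary granule list lost its call without Tshr+/+ 1 (adjusted p = 0.0548), and its median was 0.10 without Tshr+/+ 2, 0.10 without Tshr-/- 1, 0.27 without Tshr+/+ 3 and 0.29 without Tshr-/- 2. The resident macrophage list lost its call without Tshr+/+ 3 (adjusted p = 0.216), Tshr-/- 1 (0.640) or Tshr-/- 2 (0.153). Its median was -0.34 without Tshr+/+ 2, -0.36 without Tshr-/- 3, -0.08 without Tshr-/- 1 and -0.06 without Tshr-/- 2. Without both libraries labelled Tshr-/- 1 and 2, which leaves 1 library with that label, the median turned to the opposite direction (0.23). The T and NK cell list lost its call without Tshr+/+ 3 (adjusted p = 0.322), Tshr-/- 1 (0.0859) or Tshr-/- 3 (0.0509) and without both libraries numbered 3 (0.540). Its median was 0.64 without Tshr-/- 2, 0.18 without Tshr+/+ 3, 0.22 without Tshr-/- 3 and 0.07 without both libraries numbered 3. The erythroid list lost its call without Tshr+/+ 1 (adjusted p = 0.0548), Tshr+/+ 3 (0.216) or Tshr-/- 1 (0.0859). It also lost its call with no filter on low values (adjusted p = 0.945), with voom (0.140), without both libraries numbered 3 (0.121) and without the libraries labelled Tshr-/- 1 and 2 (0.309). Its median was 0.94 without Tshr+/+ 2, 0.36 without Tshr+/+ 3, 0.37 without Tshr-/- 1 and 0.007 with no filter. Without the libraries labelled Tshr-/- 1 and 2 it was 0.24.

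The other lists of cell types did not pass. Over 5 tested B cell genes the median log2 fold change was -0.40 (camera adjusted p = 0.168), with the immunoglobulin genes Igkc (478 ± 140.2 FPKM in Tshr+/+ and 268 ± 89.7 FPKM in Tshr-/-, SD, n = 3) and Jchain (35.3 ± 12.5 and 18.7 ± 6.25 FPKM) below and Ighm (60.9 ± 18.5 and 86.8 ± 16.8 FPKM) above the Tshr+/+ mean; Ighm was named after its values were seen. The median was -0.06 over 22 genes of secondary and tertiary granules (adjusted p = 0.168), 0.10 over 21 mature neutrophil genes (0.385), 0.07 over 26 monocyte genes (0.736) and -0.13 over 15 genes of dendritic cells and antigen presentation (0.468). The most abundant neutrophil transcript, S100a9, had 45613 ± 6788 and 46595 ± 10395 FPKM, and Lyz2, the lysozyme gene of myeloid cells, had 7836 ± 706 and 6995 ± 710.5 FPKM. The median was 0.01 over 16 eosinophil, basophil and mast cell genes (adjusted p = 0.337), with the mast cell protease gene Cpa3 at a log2 fold change of 0.64 ± 0.24 (SE). It was 0.16 over 6 stromal and osteoblast genes (adjusted p = 0.261) and 0.13 over 7 stem and progenitor genes (0.0900). The megakaryocyte list had a median of -0.02 over 8 genes while its mean and its test pointed upward (adjusted p = 0.736).

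At the preset correlation several of these lists passed when a library was left out. With an estimated correlation, run on all 6 libraries only, their adjusted p lay between 0.922 and 0.928. Without Tshr-/- 2 the lists of secondary and tertiary granules (median -0.19, adjusted p = 0.000426), monocytes (median 0.17, adjusted p = 0.0389), eosinophils, basophils and mast cells (median 0.25, adjusted p = 0.0209) and stem cells (median 0.20, adjusted p = 0.0252) passed. Without Tshr-/- 3 the lists of mature neutrophils (median 0.16, adjusted p = 0.00369), dendritic cells (median -0.31, adjusted p = 0.0156) and B cells (median -0.63, adjusted p = 0.0356) passed. The B cell list also passed without Tshr+/+ 2 (median -0.44, adjusted p = 0.0132). The stromal list passed with no filter on low values (adjusted p = 0.00408) and with voom (0.00180). Without both libraries numbered 3 the mature neutrophil list passed (adjusted p = 0.0115). Without the libraries labelled Tshr-/- 1 and 2 its median turned to -0.33 (adjusted p = 0.0206), and the lists of secondary and tertiary granules (1.76e-07) and monocytes (0.000573) passed.

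**Figure D3:**
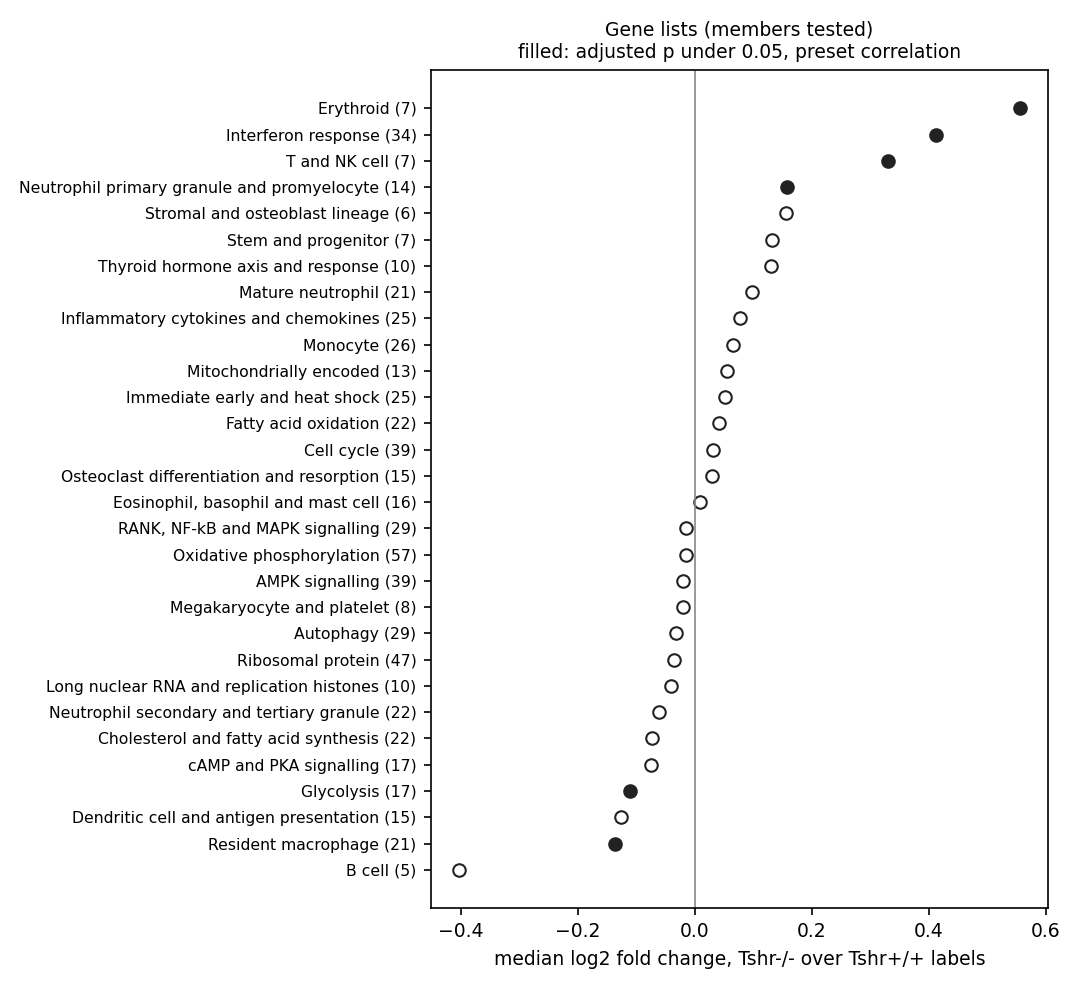
Median log2 fold change (x axis, libraries labelled Tshr-/- over Tshr+/+) of the 30 gene lists tested, with the number of tested members in brackets; filled points had a camera adjusted p under 0.05 with the preset correlation. The filled points number 6, from -0.14 for resident macrophage genes to 0.56 for erythroid genes, and with an estimated correlation 0 lists passed.

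Of the metabolic lists, glycolysis ranked lower in the libraries labelled Tshr-/- with the preset correlation. Its median log2 fold change was -0.11 over 17 genes (camera adjusted p = 0.0204, and adjusted p = 0.922 with an estimated correlation, which was 0.471). Its members included the glucose transporter gene Slc2a1 at 38.3 ± 8.82 FPKM in Tshr+/+ and 28.1 ± 0.648 FPKM in Tshr-/- (SD, n = 3) and the enolase gene Eno1 at 216 ± 7.76 and 184 ± 19.8 FPKM. That call ended without Tshr+/+ 1 (adjusted p = 0.0778), Tshr+/+ 2 (0.432) or Tshr-/- 3 (0.541) and with quantile normalization (0.101). The median was -0.25 without Tshr+/+ 3 and -0.17 without Tshr-/- 2. It was -0.06 without Tshr+/+ 1, -0.04 without Tshr+/+ 2 and -0.04 without Tshr-/- 3. The median was -0.02 over 57 genes of oxidative phosphorylation (adjusted p = 0.736), -0.07 over 22 genes of cholesterol and fatty acid synthesis (0.150) and 0.04 over 22 genes of fatty acid oxidation (0.620). The mitochondrially encoded list had a median of 0.06 over 13 genes (adjusted p = 0.0964), with the cytochrome oxidase gene mt-Co1 at 1900.1 ± 108 and 1908 ± 159 FPKM and the NADH dehydrogenase gene mt-Nd3 at 1.46 ± 0.661 and 6.50 ± 3.66 FPKM. The libraries labelled Tshr-/- 1 and 2 alone carry the mt-Nd3 mean, with 8.40 and 8.81 FPKM. Tshr-/- 3 had 2.28 FPKM and Tshr+/+ 3 had 2.18 FPKM. In fragments, mt-Nd3 had 47 and 43 in the libraries labelled Tshr-/- 1 and 2 and between 5 and 16 in the others. The pseudogene Gm28438 on chromosome 1, named after its values were seen, moved the other way. It had 11 and 6 fragments in the same libraries and between 48 and 65 in the others. Whether fragments were divided between these genes was not tested.

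Among the remaining lists the median was 0.08 over 25 genes of inflammatory cytokines and chemokines (adjusted p = 0.287), 0.03 over 39 cell cycle genes (0.736) and 0.05 over 25 immediate early and heat shock genes (0.602). It was -0.03 over 47 ribosomal protein genes (adjusted p = 0.449) and -0.04 over 10 long nuclear RNAs and histone genes (0.844). The chemokine gene Ccl2 had 21.5 ± 9.43 FPKM in Tshr+/+ and 32.5 ± 13.3 FPKM in Tshr-/- (SD, n = 3), and the cyclin gene Ccne1 had 7.85 ± 1.52 and 5.97 ± 1.14 FPKM. No member of any of the 30 lists passed over all genes, and 0 passed adjusted over the list alone. The passes that follow are at the preset correlation, while an estimated correlation, run on all 6 libraries only, gave these lists an adjusted p between 0.922 and 0.957. The mitochondrial list passed without Tshr+/+ 1 (median 0.08, adjusted p = 0.0281), Tshr-/- 1 (0.12, 0.0370) or Tshr-/- 2 (0.08, 0.0389), and by adjusted p with quantile normalization (0.0236) and with a minimum of 10 fragments (0.0161). The ribosomal protein list passed without Tshr+/+ 1 (median -0.07, adjusted p = 0.0281) or Tshr-/- 1 (-0.10, 0.00456), and the cholesterol synthesis list without Tshr+/+ 1 (-0.14, 0.000968) or Tshr-/- 2 (-0.15, 0.0209). The inflammatory list passed without Tshr+/+ 1 (median 0.21, adjusted p = 0.0376) or Tshr-/- 3 (0.20, 0.0210), and the cell cycle list without Tshr-/- 2 (0.11, 0.00576). The list of long nuclear RNAs and histones passed in the opposite direction without Tshr-/- 3 (median 0.14, adjusted p = 0.0332). Without the libraries labelled Tshr-/- 1 and 2 the lists of the cell cycle (adjusted p = 0.000573), cholesterol synthesis (0.0118), mitochondrial genes (0.00224) and long nuclear RNAs and histones (0.000492) passed.

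The libraries did not fall into groups by genotype label. The first principal component, with 46.7% of the variance, set the libraries labelled Tshr+/+ 3 and Tshr-/- 3 at 27.9 and 23.6 apart from the other 4, which lay between -21.5 and -5.46. Leaving out both libraries numbered 3, an alternative chosen after seeing the data, gave 13 higher and 11 lower genes. It drops the library labelled Tshr-/- 3, which held 1 fragment of Tshr, and keeps those labelled Tshr-/- 1 and 2. Among the higher genes were Ifit1, Ifit3 and Rsad2 of the interferon list and the basophil protease genes Mcpt8 and Prss34. The lower ones included the interferon-induced gene Ifi44l (log2 fold change -1.78), and all these were named after their values were seen. Between the dropped libraries the basophil genes went the other way. Prss34 had 94.8 FPKM in Tshr+/+ 3 and 62.4 FPKM in Tshr-/- 3, and Mcpt8 had 37.0 and 26.8 FPKM. Ifit1, Ifit3 and Rsad2 kept their direction there by a smaller margin. The libraries labelled Tshr-/- 1 and 2 also shared 6 genes that differed over 10-fold from the other 4 libraries: Itln1, Ifi202b, BC002163 and Gm3375 were higher and Ifi44l and Adgrg5 lower in both, and these genes too were named after their values were seen. Of 83 tested genes within 10 Mb of Tshr on chromosome 12, 0 were called, as were 0 of the 10830 genes elsewhere, and 3 of the 83 against 314 of the 10830 had an unadjusted p under 0.05 (Fisher's exact test, two-sided p = 0.521). Xist, the RNA of the inactive X chromosome, did not exceed 0.00553 FPKM in any library, and Ddx3y, a gene of the Y chromosome, lay between 16.2 and 27.4 FPKM.

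**Figure D4:**
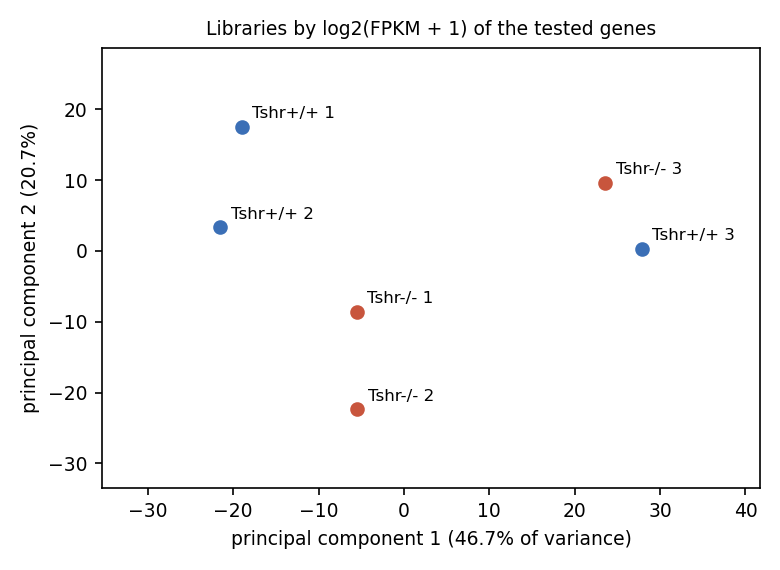
First (x axis) and second (y axis) principal components of log2(FPKM + 1) over the 10913 tested genes, 1 point per library, blue for Tshr+/+ and red for Tshr-/- labels. The libraries numbered 3 lie at 23.6 and 27.9 on the first axis, and the other 4 between -21.5 and -5.46.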

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

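All tests of this part were chosen after the values were seen. Ifi202b, an interferon-inducible gene on chromosome 1 from 173962568 to 173982744 that the filter kept out of the comparison, had 164 fragments in the library labelled Tshr-/- 1 and 82 in Tshr-/- 2, against 0 in Tshr-/- 3 and in each Tshr+/+ library. Itln1, an intestinal lectin gene on the same chromosome from 171518122 to 171535294, also outside the comparison, had 15 and 20 fragments in the libraries labelled Tshr-/- 1 and 2 and 0 in the other 4. A first search for genes with at least 10 fragments in all 3 libraries labelled Tshr-/- and 0 in the Tshr+/+ libraries found 0 genes; it was then widened to at least 10 fragments in any of the 3.

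These genes belong to a wider pattern that parts the libraries labelled Tshr-/- 1 and 2 from the others: over the 15 pairs of libraries, that pair held 6 genes more than 10-fold above or below the other 4 libraries (4 above and 2 below), such as Ifi44l with 0 fragments in both and 56, 57, 162 and 182 in the others. The highest number in the other 14 pairs was 1, which argues against counting noise. Differences of 3-, 4- and 10-fold were looked at before 10-fold was taken, and at 4-fold the pair held 11 genes against 10 for Tshr+/+ 3 with Tshr-/- 3, so the contrast with other pairs rests on the 10-fold count. Another strain background in the animals of Tshr-/- 1 and 2 may account for such genes, but the 17 placed genes at a 3-fold difference were not shown to lie closer together than random genes (4 had a neighbour within 5 Mb against a mean of 1.49, permutation p = 0.156), which a wholly different strain would also give. The table holds no sequence that would show a strain, and the genotype itself stays open, untested.

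The same libraries are those labelled Tshr-/- that kept Tshr, with 40 and 25 fragments against 1 in the library labelled Tshr-/- 3. In a resampling of these counts, prompted by their uneven spread, no draw was as uneven. The resampling p was 1e-05, the smallest that 100000 resamples can give. It covers counting error only, so a level of the allele that varies between animals stays open. An exchange of a library between the 2 groups stays open. By a rule written after the values were seen, far more fragments in the lowest Tshr+/+ than in the lowest Tshr-/- library would count against it. The counts of 45 and 1 met that rule. The rule covers only a partner that lacks Tshr, as the library labelled Tshr-/- 3 does, and such a library is missing from Tshr+/+. At 0.405 FPKM the lowest Tshr+/+ library lay below the 0.414 FPKM of the library labelled Tshr-/- 1, so other exchanges are not covered. Animals that were not homozygous remain a candidate explanation: Tshr was at 0.831 times the Tshr+/+ mean in the library labelled Tshr-/- 1 and at 0.596 times in Tshr-/- 2, and no value in the table tells a heterozygous from a wild-type locus or a transcribed mutant locus. A biological difference between these animals in the transcription of the mutant locus was not tested.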

How the results depend on the processing

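Of the 6 lists that passed, the interferon list passed in all 19 alternatives with the preset correlation (median 0.26 to 0.58, adjusted p at most 0.000573), while 0 lists passed with an estimated correlation and 0 with fry (smallest adjusted p 0.766 and 0.935). With the replicate number as a block 0 genes were called and 5 lists passed; beyond the T and NK cell list, the block changed no call. Array weights called 13 higher and 11 lower genes. Leaving out both libraries numbered 3, an alternative chosen after seeing the data, gave the same numbers (13 and 11). The genes were mostly others, with only Ifit3, Gm44782 and Mir6399 in both sets, and the cause was not tested. With 1 library left out, between 0 and 2 genes were higher, 0 lower, and between 3 (without Tshr+/+ 3) and 13 lists (without Tshr-/- 2) passed. Leaving out the libraries labelled Tshr-/- 1 and 2, chosen after seeing the data, leaves 1 library assumed to vary like the others: 0 genes and 13 lists passed, and the median turned to 0.23 for resident macrophage (adjusted p 0.00224) and to -0.33 for mature neutrophil genes (0.0206), both past the threshold and opposite to the direction with all 6 libraries; the cause was not tested. With 1 library left out, the median of long nuclear RNAs and histones ran from -0.17 to 0.14, positive without Tshr-/- 3; the cause was not tested. At an unadjusted p under 0.05, 3, 1 and 6 genes lay within 10, 5 and 20 Mb of Tshr, another threshold chosen after seeing the data. Of 2114 values of the named genes under alternatives, 9 passed the threshold, 8 of them with array weights, and 69 uncalled values changed sign. The lower mean of Tshr in the libraries labelled Tshr-/- held in each scaling, with the block (-0.258 FPKM) and without each library (differences from -0.346 to -0.143 FPKM). The DESeq2 alternative had been planned only for a file of counts and was not run; the whole fragments computed from FPKM were tested with voom instead. Among the tested genes, 425 rest on under 10 fragments.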

Other observations

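The immunoglobulin segments were picked after their values were seen, the test of strain background and the division of the summed lists into parts were chosen after the result was seen; the counts over splits of the libraries and the test of single libraries were set before their results were seen. The wording of the test of other cell types was amended after the values of single libraries had been seen, though before its own result was computed. Immunoglobulin segments, transcribed in B cells and plasma cells, which selection for CD11b should mostly remove, were mostly lower in the libraries labelled Tshr-/-: of 110 tested V and C segments 75 had a lower and 35 a higher mean log2 value, with a median log2 fold change of -0.25. In 19 of them all Tshr-/- values lay below all Tshr+/+ values, where chance gives 10% without overlap in either direction, and limma called 0 of the 110. In 5 of the 10 splits of the 6 libraries into 3 and 3 the median of these segments was as far from 0 (highest other split 0.59), and 10 splits are too few for a share under 0.05.

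A single library as the whole cause of the higher interferon list is argued against by the lowest median with 1 library left out, 0.305, with the test at the preset correlation still passed. More lymphoid or dendritic cells stay open, although selection for CD11b should leave B cells and most T cells as carry-over only: the summed FPKM of the B cell, T and NK cell and dendritic cell lists without interferon genes changed by -264 ± 173 FPKM (SE), where a rise of 26.2 FPKM had been set as the least that would fit, but Igkc alone changed by -210.1 ± 96.1 FPKM (SE) and the sum without Igkc by -53.8 ± 93.8 FPKM (SE), while by list the B cell part changed by -201.6 ± 112.6 FPKM (SE), the dendritic part by -70.8 ± 91.6 FPKM (SE) and the T and NK cell part by 8.50 ± 5.31 FPKM (SE), so that bound on the sum was wrongly set and decides nothing about T and NK cells. Another strain background in the animals of Tshr-/- 1 and 2 may contribute: the list mean in the library labelled Tshr-/- 3 lay 0.244 above the Tshr+/+ mean, against 0.63 and 0.55 in the other libraries with that label, and 1 library cannot decide. With equal totals, median-of-ratios and quantile scaling the median was 0.46, 0.42 and 0.42 and the list passed at the preset correlation. Equal totals and median-of-ratios multiply all genes of a library by 1 factor. On the log2(FPKM + 1) scale that shifts low values less than high ones, so they test a rank against other genes only to that extent. Quantile scaling can move that rank, and it changed the calls of the glycolysis and mitochondrial lists but not that of the interferon list. At the preset correlation only, that argues against the scaling as the whole cause. The genotype stays among the open explanations, gene length and GC content were not tested, and for variants near Tshr only the calls near that gene were counted, which says nothing about the interferon list.

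For the interferon list, the real split gave a median log2 fold change of 0.41 and the highest of the other splits 0.35 (0.32 among those that also part all 3 pairs of the same number); 1 of the 10 splits reached the real value. For the lists, 8 of the 10 splits gave at least the 6 lists of the real split, with 15 lists in the highest of the others, and 9 in the highest of those that part all 3 pairs. For single genes the count of splits says nothing: limma called 0 genes in the real split, so that 10 of 10 splits had to give as many, and the highest other split called 3 (0 among those that part all 3 pairs). With 10 splits no share can fall under 0.05. At an unadjusted p under 0.05 the splits that keep the libraries numbered 3 together gave 1983, 1877, 751 and 354 genes, against 317 for the labels and between 98 and 479 in the splits that part them, among them 419. The highest counts point to a structure of the samples, which the libraries numbered 3 do not account for in every split. Explanations listed for the position of the libraries numbered 3, and a lower number of B-lineage cells as an explanation of the immunoglobulin segments, were not tested.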
